A study of Drosophila melanogaster with 6 samples.

How the data were processed

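Total RNA of dm4 mutant larvae and of control larvae was extracted, amplified, coupled to Cy3 or Cy5 and hybridised to 2-colour arrays, per the labels' protocols. The design text describes 3 independent mutant replicates against one common control reference, each repeated with exchanged dyes. The deposited values are treated as log2 ratios of the channels: the sources used here give neither the log base nor the normalization method, and base 2 was taken by convention. The median of each array lay between -0.0086 and 0.0135 over all features with a value, so the values were already close to centred. The arrays of each dye-swap pair correlated positively, so the deposited ratios were taken as already turned the same way and no sign was changed. The direction, mutant over control, is likely and rests on the mutant being channel 1 in both orientations. Scanner intensities, signal over background and spot flags were not used here.

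The table held 12144 features. The 160 features for plant and genomic control spots had no values and were left out. The platform annotation named 9917 features with 1 gene and 625 with several, and 1602 were unnamed here, control spots included. Of the features with 1 gene, 9746 matched the RefSeq gene table of the Release 6 assembly by gene identifier, and 0 symbols had to be updated. That table was used for names, chromosomes and neighbours, and no coordinates are given because the build of the array annotation is not given in the sources used here. Features with several genes or none kept their own identifier.

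A feature entered the fit when it had a value on all 6 arrays, which held for 7142 of them; 2604 had values on some arrays and 2238 on none. Features of one gene were averaged, which gave 6504 transcripts, 5348 of them named. Of 593 genes with several features, 20 had features that differed by over 1 on the log2 scale, and 15 of these had opposite signs. The arrays of a pair were averaged, as the design text describes, and the 3 pair means were tested against 0 with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all transcripts and a threshold of 0.05. The control larvae enter only as one reference, so p-values leave out the spread between control collections. The median standard error of a mean log2 ratio was 0.07.

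In simulated data for 6504 transcripts with 3 pair means, limma recovered 98% of 50 genes changed by 2-fold, 100% of 50 changed by 4-fold, 76% of 50 changed by 1.41-fold and 6% of 50 changed by 1.19-fold, and 4.11% of its calls were false. The camera test called 5 of 5 simulated lists shifted by 0.4 and 0 of 20 unshifted lists, and the permutation of neighbouring genes gave a p under 0.05 in 2 of 40 random sets. The limma simulation changed a far smaller share of transcripts than the 61.7% called in the data. Simulated genes were drawn independently, with variances from limma's own fit. These rates therefore need not hold for the data, and correlation between genes was not simulated.

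Gene lists were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01, for lists with at least 5 measured genes, with adjustment over the 30 lists tested. With the correlation estimated from the residuals, camera passed 0 lists, and 2 had an unadjusted p under 0.05. That setting rests on the very few residual degrees of freedom that 3 pair means leave. Hardly any list could pass with it, so it cannot decide against a shift. fry, which tests whether the genes of a list move one way without comparing them with other genes, passed 19. X-linked genes and genes within 500 kb of the mutated gene were tested in the same way. The rule for named genes, also fixed beforehand, took the 12 largest decreases and the 12 largest increases among named genes that passed with 1 sign on all 6 arrays. It also took every passing gene of the dMyc network list, and up to 4 members of a passing list in its direction or up to 2 of another list, by smallest p. Further list members that illustrate a count were named after their values were seen. The dye effect was 0.5 times the difference between the arrays of a pair and was tested in the same way.

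Alternatives were leaving out each replicate, centring or scaling the arrays, fitting all 6 arrays with the replicate as a random block with and without a dye term, and using one dye orientation only. Others were a looser filter on missing values, features not averaged, a robust variance prior, an estimated correlation and a rank-based list test. The planned level of the mutated gene was not run, since no feature was named as it. Permutations numbered 10000 and bootstrap draws 2000, with intervals of 95%. Figures were drawn with matplotlib.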

Results

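Transcript levels were compared between Drosophila melanogaster larvae carrying dm4, described in the labels as a null for dMyc, and control larvae of a matched genetic background, all at 24 h after egg deposition. dMyc is the fly member of the Myc family of transcription factors, known for its role in growth. Total RNA from 3 independent collections of mutant larvae was amplified and hybridised to 2-colour arrays against one common control reference. Each collection was measured again with the dyes exchanged, so the data hold 6 arrays and 3 replicates. Between 8377 and 9197 of 11984 gene features had a value on an array. After features of a gene were averaged, 6504 transcripts had values on all 6 arrays. Of these, 5348 carried a gene name, and the number of arrays limits the precision. Values below are log2 ratios of mutant over control, as mean ± SD of the 3 dye-swap pairs. The log base is not given in the sources used here and was taken as 2. The direction is likely, since the mutant is channel 1 in both dye orientations and the deposited ratios of each dye-swap pair already run the same way.

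The main comparison asked which transcripts differ in larvae without dMyc. Of the gene lists tested, ribosome biogenesis and the nucleolus had the lowest median, -1.94. In that list Nop60B, the pseudouridine synthase that modifies ribosomal RNA, stood at -3.77 ± 0.20 (SD, n = 3), and NHP2, a core protein of the same class of particles, at -3.45 ± 0.21. Prat2, which encodes an enzyme of the first step of purine synthesis, rose most, to 3.54 ± 0.47. Across the array 2029 transcripts were lower and 1984 higher with limma at an adjusted p under 0.05, which is 61.7% of those tested. The arrays were already close to centred on 0, so similar counts on both sides are largely built in. They cannot show whether the total amount of RNA changed. By at least 1.5-fold 825 transcripts were lower and 459 higher, and by at least 4-fold 58 were lower and 12 higher; which side is the larger rests on the likely direction of the ratios. The smallest change that passed was 1.12-fold. One common control reference served all arrays, so the test leaves out the spread among control larvae. Mutant and control larvae were matched by age, and whether they had reached the same stage was not tested.

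Among the 12 named genes with the largest decreases were Nopp140, a nucleolar phosphoprotein, at -2.98 ± 0.15, and CG12288 and CG8545, both in the ribosome biogenesis list, at -3.05 ± 0.12 and -3.02 ± 0.51. Art8 and Art3, of the protein arginine methyltransferase family, stood at -3.56 ± 0.24 and -2.99 ± 0.19. CG2187 was at -3.67 ± 0.01 and CG8664 at -3.52 ± 0.19. The lipase family genes CG6283 and CG6295 were at -3.47 ± 0.50 and -3.14 ± 0.52. The remaining gene, the cytochrome P450 Cyp28a5, was at -3.20 ± 2.19, and the size of its decrease depended on replicate 3. Without that replicate its mean was -1.94 and it still passed (limma, adjusted p = 1.3e-05). With all replicates and a robust variance prior, limma's adjusted p for Cyp28a5 was 0.133. The adjusted p of the other 11 lay between 4.6e-07 (CG2187) and 1.6e-05 (CG8545).

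Among the 12 largest increases, CG30029 followed Prat2 at 3.33 ± 0.88, and EAChm, an enhancer of the acetyltransferase Chameau, was at 3.07 ± 0.44. Cyp4p2, a cytochrome P450, rose to 2.44 ± 0.59 and Lip4, a lipase of the starvation and FOXO list, to 2.17 ± 0.17. CG18649 was at 2.12 ± 0.16, CG4306 at 2.09 ± 0.19, CG3604 at 1.89 ± 0.12 and slf, a cuticle gene, at 1.88 ± 0.26. The antifungal peptide gene Drs was at 2.22 ± 1.26 and the heat shock gene Hsp70Ab at 1.95 ± 0.96, each with its highest value in replicate 3 (3.65 and 3.06). With a robust variance prior the call for Drs was lost (limma, adjusted p = 0.0653). CG31224 averaged 1.95 ± 0.03, but its separate features gave 0.85 and 3.04.

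**Figure D1:**
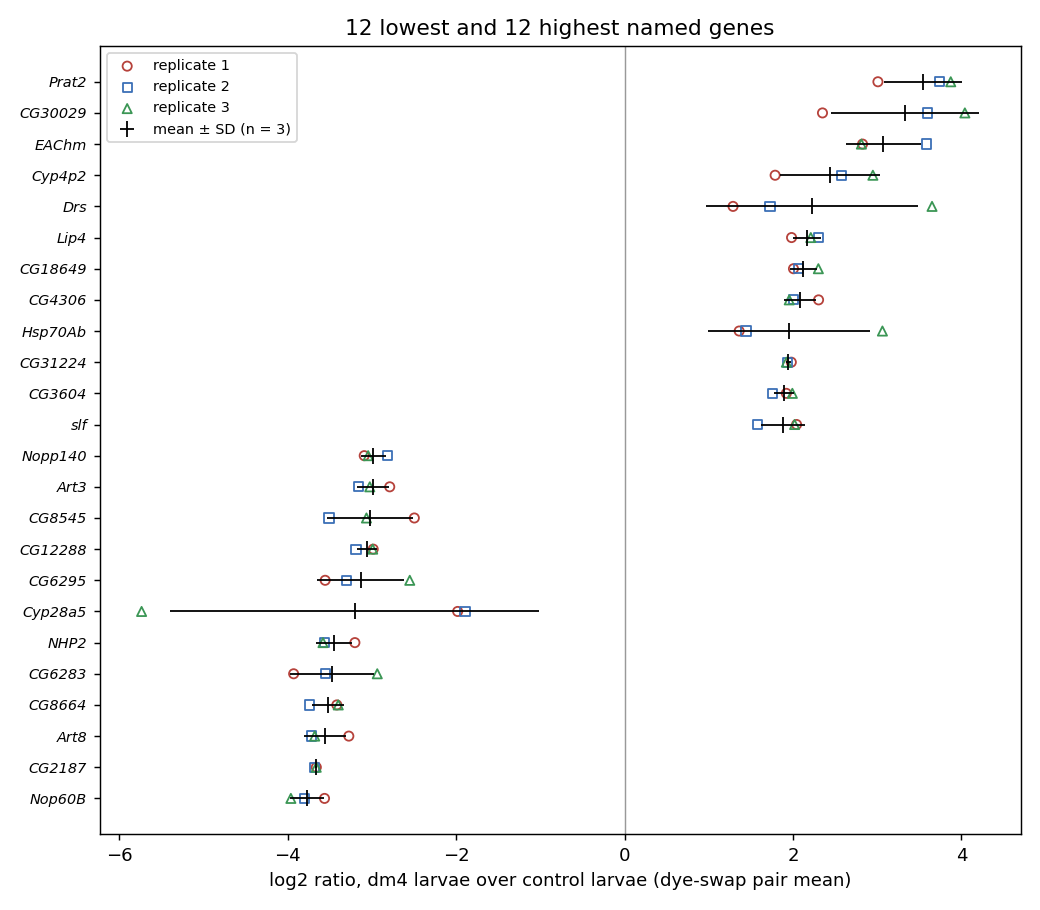
Log2 ratio of mutant over control larvae for the 12 named genes with the largest decreases and the 12 with the largest increases, with one symbol per replicate and a bar for the mean ± SD of 3 dye-swap pairs. Cyp28a5, Drs and Hsp70Ab have one replicate apart from the others, while CG2187 lies at -3.67 ± 0.01.

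Gene lists fixed beforehand were then compared with the rest of the named genes by limma's camera test. The correlation between genes was preset at 0.01, and 30 of 32 lists had enough genes. Adjusted p with an estimated correlation is given beside it. With 3 pair means that setting has very few residual degrees of freedom. Hardly any list could pass with it, so it cannot decide against a shift. The lists of the protein synthesis machinery fell. Of 43 measured genes for ribosome biogenesis and the nucleolus, 41 fell and 1, nom, rose, with a median of -1.94 (camera, adjusted p = 9.1e-20; adjusted p = 0.42 with an estimated correlation). nom, at 0.31 ± 0.13, did not pass without replicate 2 or replicate 3 (limma, adjusted p = 0.0748 and 0.0660). It was listed by its symbol, and whether it acts in ribosome biogenesis was not checked here. Nop56, a core protein of the particles that methylate ribosomal RNA, stood at -2.98 ± 0.03. Cytosolic ribosomal protein genes, drawn by symbol pattern, fell in 30 of 31 cases with a median of -1.13 (camera, adjusted p = 1.1e-11, and 0.42 with an estimated correlation). The pattern also took in RpLP0-like, RpL7-like and RpL24-like, at -2.33 ± 0.30, -2.16 ± 0.10 and -1.51 ± 0.11. RpLP0-like is in the ribosome biogenesis list too. Whether they encode ribosomal proteins was not checked here, and without them the median was -1.03. RpL41 was at -1.88 ± 0.04, RpL27 at -1.66 ± 0.11 and RpL34a at -1.60 ± 0.13, while RpLP1, at -0.02 ± 0.13, did not pass. All 10 measured genes of RNA polymerases I and III fell, with a median of -1.34 (camera, adjusted p = 1.1e-05; adjusted p = 0.52 with an estimated correlation), but Polr3I, at -0.17, did not pass without replicate 2 or replicate 3 (limma, adjusted p = 0.252 and 0.150). The polymerase I subunit genes Polr1B, Polr1A and Polr1F were at -2.47 ± 0.31, -2.03 ± 0.16 and -1.72 ± 0.08.

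Translation factor genes fell in 29 of 31 cases, with a median of -0.83 (camera, adjusted p = 8.1e-10; adjusted p = 0.52 with an estimated correlation). eEF5 stood at -1.41 ± 0.04 and eIF3b at -1.39 ± 0.17, and eIF4E4, at 0.19 ± 0.09, was the 1 member that rose, a call lost without any 1 of the replicates (limma, adjusted p between 0.0768 and 0.212). Of 23 aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 20 fell, with a median of -0.81 (camera, adjusted p = 4.7e-07; adjusted p = 0.55 with an estimated correlation). TyrRS was at -1.31 ± 0.07, and the 3 that did not pass were the mitochondrial GluRS-m, ProRS-m and ValRS-m. All 8 genes of the CCT chaperonin, which folds actin and tubulin, fell with a median of -1.03 (camera, adjusted p = 6.3e-05; adjusted p = 0.55 with an estimated correlation). Decreases were smaller for mitochondrial ribosomal proteins, where 43 of 59 fell and 4 rose with a median of -0.36 (camera, adjusted p = 3.5e-06, and 0.57 with an estimated correlation). Without replicate 1, 47 of these genes fell and 3 rose. Without replicate 2, 33 fell and 1 rose, and without replicate 3, 29 fell and 1 rose. In the proteasome 21 of 27 fell with a median of -0.35 (camera, adjusted p = 4.3e-05, and 0.59 with an estimated correlation), led by Prosbeta3 at -1.02 ± 0.13. Without replicate 1, 26 proteasome genes fell, without replicate 2, 14, and without replicate 3, 13.

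Digestive enzyme genes were lower, with 18 of 25 down and 3 up at a median of -0.53 (camera, adjusted p = 0.00103; adjusted p = 0.52 with an estimated correlation). The serine protease genes yip7, Jon44E, Jon99Ci and thetaTry stood at -1.79 ± 0.24, -1.56 ± 0.09, -1.41 ± 0.11 and -1.33 ± 0.16. Many genes of this list carry Jon symbols. Cross-hybridisation between similar members was not tested, so their ratios may not be independent. The 3 that rose, Mal-A1, Mal-A3 and Mal-A4, encode maltases, and 1 of them passed without replicate 2 or replicate 3. In the fat body list 5 of 6 genes fell, among them FASN1, the fatty acid synthase, at -0.95 ± 0.22 and the lipid droplet gene Lsd-1 at -1.23 ± 0.42, and Obp44a rose to 1.02 ± 0.27. The list did not pass (median -0.79; camera, adjusted p = 0.0541). The lipoprotein gene apolpp averaged -1.12 ± 0.11 from features at -1.94 and -0.31. Of 10 lipid synthesis genes 7 fell, with AcCoAS, which makes acetyl-CoA, at -1.07 ± 0.06 and ATPCL, which makes it from citrate, at -0.87 ± 0.11, and Lpin rose to 0.58 ± 0.17. That list did not pass either (median -0.47; camera, adjusted p = 0.0582). Both of these lists passed when the replicate was a random block in limma (camera, adjusted p = 0.0376 for fat body and 0.0386 for lipid synthesis). The fat body list also passed without replicate 3 (camera, adjusted p = 0.0429). With an estimated correlation both lists had an adjusted p of 0.52 (camera).

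Muscle, neuron and glia genes were higher. Of 18 muscle genes 14 rose and none fell, with a median of 0.52 (camera, adjusted p = 8.7e-05; adjusted p = 0.52 with an estimated correlation). The myosin light chain gene Mlc2 stood at 0.97 ± 0.08, the muscle LIM protein gene Mlp60A at 0.95 ± 0.09 and the actin gene Act87E at 0.76 ± 0.13. Of 11 neuron genes 7 rose, with a median of 0.30 (camera, adjusted p = 0.0249; adjusted p = 0.60 with an estimated correlation). The tyrosine hydroxylase gene ple was at 0.77 ± 0.17 and the calcium channel gene cac at 0.47 ± 0.09, while the synaptic genes nSyb and unc-13, at -0.05 ± 0.09 and -0.03 ± 0.08, did not pass. Without replicate 2, 5 neuron genes rose, and without replicate 3, 4. The calls for Sh and Rab3 were lost without replicate 2 and also without replicate 3. nrv3, at 0.54 ± 0.26, stood at 0.01 with the looser filter on missing values (limma, adjusted p = 0.956). Whether the genes of this list rose within neurons was not tested. Of 7 glia genes 5 rose, with a median of 0.33 (camera, adjusted p = 0.0254; adjusted p = 0.55 with an estimated correlation), among them loco at 0.46 ± 0.07 and nrv2 at 0.61 ± 0.24. Larval cuticle genes rose in 22 of 36 cases and fell in 5, with a median of 0.40 (camera, adjusted p = 0.00245; adjusted p = 0.59 with an estimated correlation). Cpr47Eb was at 0.98 ± 0.26 and Cpr57A at 0.88 ± 0.05; without replicate 2 or replicate 3, 3 and 2 cuticle genes fell. The starvation and FOXO list had 10 of 15 genes up and 3 down at a median of 0.41 (camera, adjusted p = 0.0336; adjusted p = 0.55 with an estimated correlation). ImpL2, a secreted binder of insulin-like peptides, was at 1.09 ± 0.14 and the nuclear receptor gene Hnf4 at 0.53 ± 0.03, while sugarbabe (sug) fell to -1.25 ± 0.26. With only the arrays that had the mutant in Cy3, the cuticle and starvation lists both had an adjusted p of 0.0570 (camera), and the starvation list had 0.0592 with the looser filter on missing values.

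**Figure D2:**
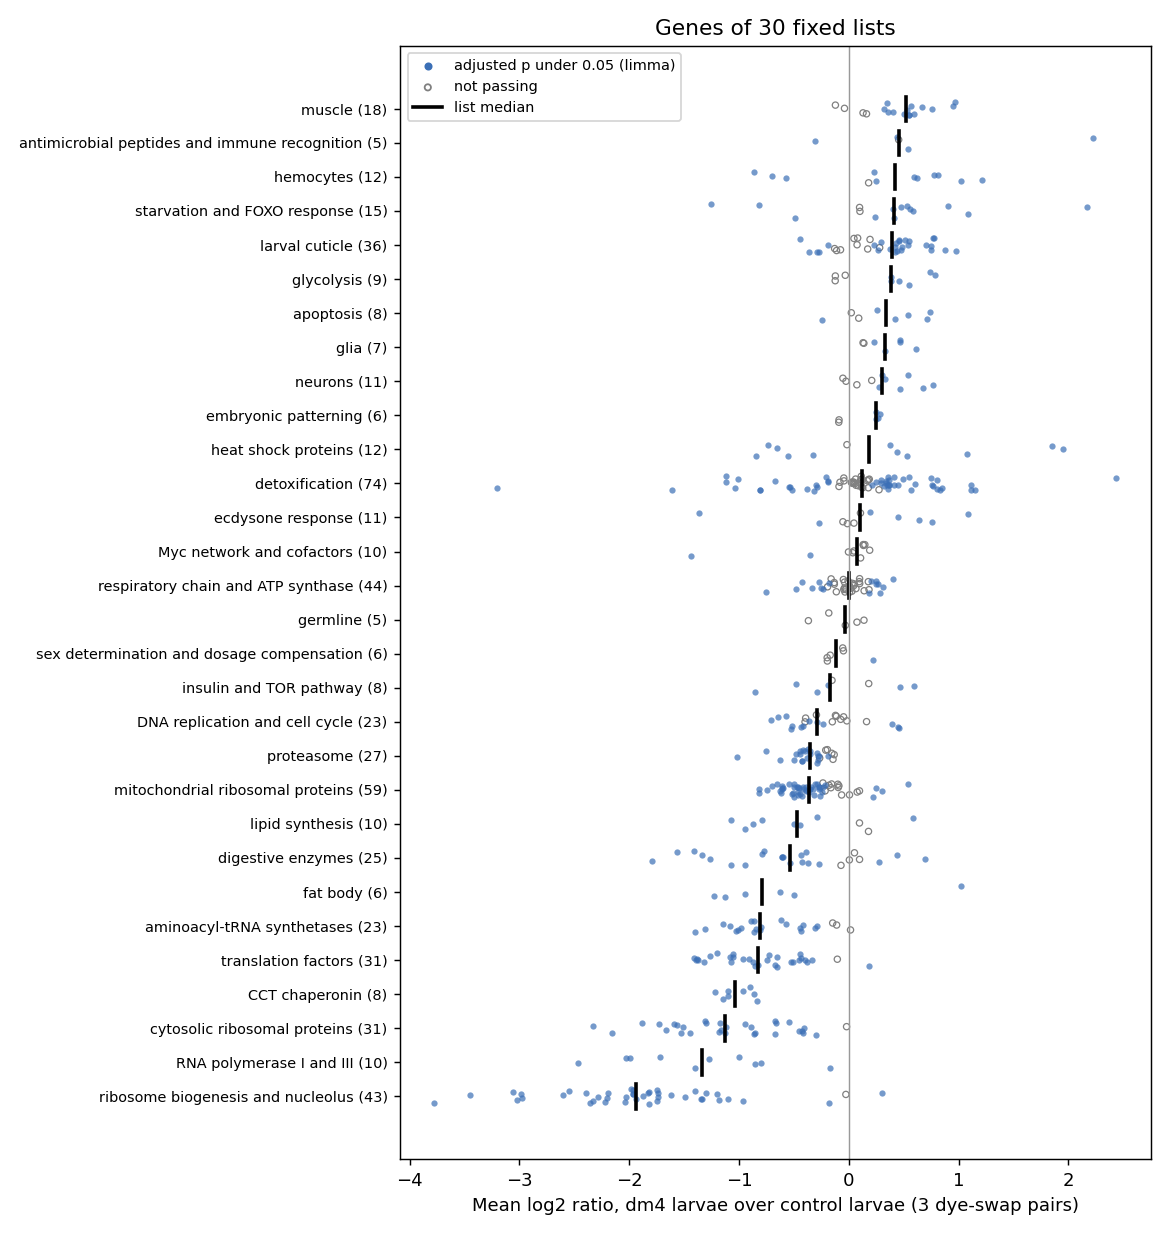
Mean log2 ratio of mutant over control larvae for each gene of 30 lists, with filled points for genes that passed in limma, open points for those that did not, and a bar at each list median; counts of measured genes follow the list names. Medians run from -1.94 for ribosome biogenesis to 0.52 for muscle.

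The remaining lists did not pass. Of 9 glycolysis genes 6 rose and none fell (median 0.39; camera, adjusted p = 0.0586), with Pglym78 at 0.79 ± 0.04 and Tpi at 0.54 ± 0.14; without replicate 3 the list passed (adjusted p = 0.0359). Of 8 apoptosis genes 5 rose and 1, p53, fell (median 0.34; camera, adjusted p = 0.0554), and skl, a cell death inducer, was at 0.74 ± 0.10; without replicate 2 the list passed (adjusted p = 0.0470) and p53 did not (adjusted p = 0.0796). The detoxification list, drawn by symbol pattern, split into 31 higher and 19 lower of 74 (median 0.12, camera, adjusted p = 0.0635, and 0.0470 without replicate 2). GstE6 was at 1.15 ± 0.10 and Cyp4ad1 at -1.12 ± 0.12. The pattern also took in the cyclophilin genes Cyp1, counted as lower at -0.31 ± 0.12, and Cyp40, which did not pass. The list was not tested without them. Of 12 hemocyte genes 8 rose and 3 fell (median 0.42; adjusted p = 0.0957): Pxn was at 1.02 ± 0.20 and Ppn at 0.77 ± 0.09, while vkg was at -0.86 ± 0.14. Of 5 immune genes 3 rose and 1, Mtk, fell (median 0.45; adjusted p = 0.192), with Rel, an NF-kappaB factor, at 0.54 ± 0.14; without replicate 2, Mtk did not pass (limma, adjusted p = 0.215).

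Of 12 heat shock genes 6 rose and 5 fell (median 0.18, or 0.073 without replicate 3; camera, adjusted p = 0.914), with l(2)efl, a small heat shock gene, at 1.85 ± 0.15 and Hsp60A, a mitochondrial chaperonin, at -0.84 ± 0.10. In the ecdysone list 5 of 11 rose and 2 fell (median 0.11; adjusted p = 0.220), with Kr-h1 at 0.64 ± 0.04; without replicate 2, 1 fell. Of 8 insulin and TOR genes 2 rose and 4 fell (median -0.17; adjusted p = 0.671). Ilp2, an insulin-like peptide, rose to 0.60 ± 0.10 and slif, an amino acid transporter, fell to -0.85 ± 0.13. In the respiratory chain and ATP synthase list 8 of 44 rose and 8 fell, with a median of 0.01, a mean of -0.02 and a test direction upward (adjusted p = 0.924). ATPsynbetaL was at -0.76 ± 0.13; between 3 and 5 genes of this list rose when 1 replicate was left out, while 12 fell without replicate 1 and 4 without replicate 2 or replicate 3. Embryonic patterning genes rose in 4 of 6 cases, kni at 0.27 ± 0.08 among them (median 0.25; adjusted p = 0.260), but in 0 by limma without replicate 2 and in 1 without replicate 3. None of 5 germline genes passed by limma (median -0.03; adjusted p = 0.924), and without replicate 1, 1 of them, piwi, was higher. vas, the 1 with an unadjusted p under 0.05, stood at -0.18 ± 0.11 (adjusted p = 0.0535) and was lower by limma with the replicate as a random block, with or without a dye term, with the arrays scaled to one spread and with the mutant in Cy3 only (adjusted p between 0.0141 and 0.0443). Of 6 sex determination genes 1, msl-3, rose to 0.22 ± 0.04 (list median -0.11, and from -0.15 to -0.046 over the replicates left out; adjusted p = 0.671). msl-3 did not pass without replicate 2 or replicate 3 (limma, adjusted p = 0.105 and 0.0681), and 2 genes of the list were lower without replicate 1. The tracheal list held 4 measured genes, 3 of them higher, and was not tested, and 0 odorant and gustatory receptor genes had values on all arrays. Counts adjusted over the list alone were the same as those over all genes tested except in the proteasome (24 lower), muscle (15 higher), the respiratory chain (2 higher and 4 lower), the insulin and TOR list (3 higher) and sex determination (0 higher).

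The DNA replication and cell cycle list differed between replicates. Of 23 genes 10 fell and 3 rose, with CycD, a cyclin of the first gap phase, at -0.52 ± 0.10 and the replicative helicase gene Cdc45 at -0.71 ± 0.40. The mitotic genes pim, fzy and Klp61F were the 3 that rose, and pim stood at 0.46 ± 0.11 but did not pass with only the mutant in Cy5 (limma, adjusted p = 0.566). Without replicate 2 or replicate 3, 6 genes fell. The list median was 0.01 in replicate 1, -0.38 in replicate 2 and -0.42 in replicate 3. The list did not pass (camera, adjusted p = 0.123, and 0.68 with an estimated correlation). It passed without replicate 1 at the preset correlation (camera, adjusted p = 0.0113). PCNA, the replication clamp, had 0.33 in replicate 1 against -0.78 and -0.73 in the others, and did not pass (limma, adjusted p = 0.136).

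**Figure D3:**
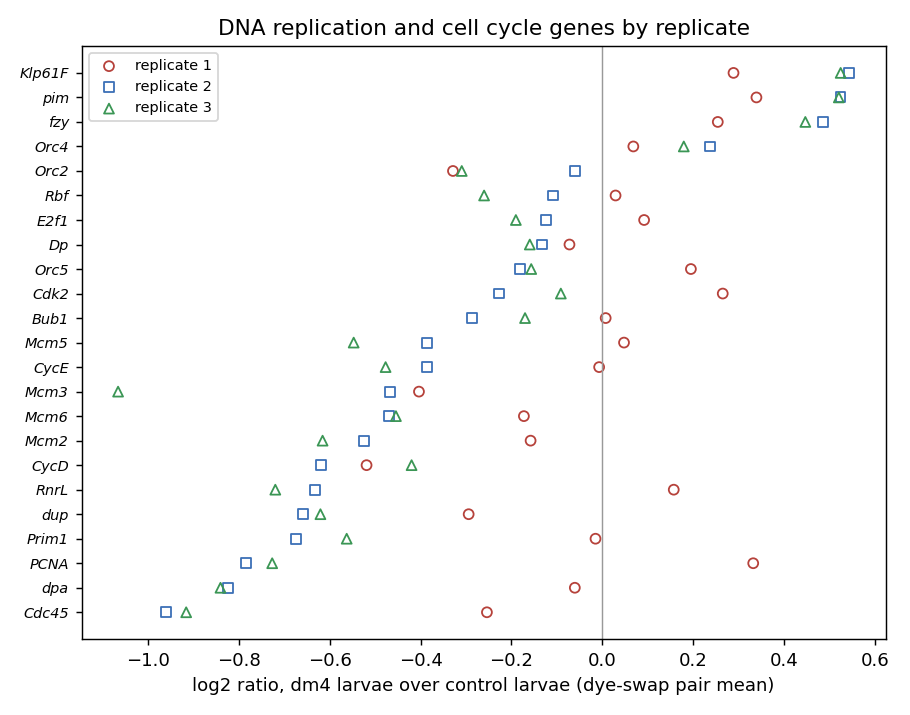
Log2 ratio of mutant over control larvae for the 23 measured DNA replication and cell cycle genes, with one symbol per replicate (mean of a dye-swap pair). Replicate 1 has a median of 0.01, and replicates 2 and 3 have medians of -0.38 and -0.42.

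Partners and cofactors of dMyc were examined next. Of 10 measured genes 2 passed, and both were lower; without replicate 1, 2 further genes were higher. pont, which encodes a helicase cofactor, stood at -1.43 ± 0.09 and Mnt, the repressor that also pairs with Max, at -0.35 ± 0.09 (limma, adjusted p = 7.9e-06 and 0.00353). Max itself, the shared partner, was at -0.00 ± 0.13 and did not pass. The list median was 0.08 and its mean -0.10, with a test direction upward (camera, adjusted p = 0.907). No feature was named as the mutated gene in the annotation used here, so its level is not reported as such. The unnamed feature LD32539, chosen after its values were seen, had the largest decrease of all transcripts tested, -6.13 ± 0.09 (limma, adjusted p = 5.4e-08), with values from -7.34 to -5.02 on the 6 arrays.

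Because the mutated gene lies on the X chromosome, X-linked genes and its neighbours were compared with the other genes. The 781 X-linked genes had a median of -0.03 and the 4470 genes of the large autosome arms a median of 0.01 (camera, adjusted p = 0.361). Among 18 measured genes within 500 kb of the mutated gene, 10 rose (55.6%) and 5 fell (27.8%), with a median of 0.22 (camera, adjusted p = 0.361). Of the autosomal genes 31.3% rose and 31.1% fell. The difference in these shares was not tested. The comparison was planned because mutant and control larvae may differ in sex or in linked background. It does not measure either directly, so both stay open.

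The dye-swap design also gave the part of each ratio that follows the dye. With limma, 185 transcripts (2.84%) had a dye effect, 10 of them by at least 1.5-fold, and the median size of the dye effect was 0.06 against 0.27 for the ratio itself. Without replicate 1 the count was 344, and without replicate 2 or replicate 3 it was 0 by limma, with 1254 and 678 at an unadjusted p under 0.05. Across genes, which are not independent replicates, the pair means of the replicates correlated with a Pearson r of 0.911 for replicates 1 and 2, 0.908 for 1 and 3 and 0.955 for 2 and 3. The common control reference enters every pair mean, so part of this agreement can come from the reference. The dye-swapped arrays of replicate 1 correlated less closely (0.810) than those of replicate 2 (0.906) and replicate 3 (0.900).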

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

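The values here come from features left out of the comparisons because a value was missing on at least 1 array; they are given because all their values exceeded 2 in size on the log2 scale, ran one way and came from all 3 replicates. These features have no test, and no explanation was tested. Lower in mutant larvae were pit, a helicase gene of the nucleolus, with a mean of -2.20 over 5 arrays, and Polr1E, of RNA polymerase I, with a mean of -2.19 over 5 arrays. Other features of pit had values on all arrays and entered the comparisons, where pit averaged -1.10 ± 0.03 (limma, adjusted p = 1.6e-05) from features at -2.50 and 0.30. The receptor gene mthl8 had a mean of -3.15 over 5 arrays, the unnamed feature Eisenman_4 had -4.37 over 5 arrays, and the unnamed feature RH27492 had -2.29 over 3 arrays. Cyp304a1, a cytochrome P450 gene, was higher, with a mean of 3.02 over 5 arrays and single values from 2.00 to 4.22.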

How the results depend on the processing

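The alternatives without Obp44a, without ribosomal protein symbols ending in -like and without genes whose features differ by over 1 were chosen after seeing the data. The fat body list had a median of -0.95 without Obp44a, but that gene was the 1 member that rose, so leaving it out lowers the median by construction and no test is given. The cytosolic ribosomal proteins had a median of -1.03 and still passed (camera), and the counts were 2014 lower and 1980 higher transcripts. The counts of changed transcripts, at any size and at 1.5-fold, stayed within 1.5 times their main values in every alternative run. At any size between 1549 and 2257 were lower and between 1394 and 2195 higher. The highest counts rest on larger totals than the 6504 of the main fit. The 2257 came from 8259 transcripts with the looser filter, and the 2195 from 7142 features that were not averaged. Without replicate 2, 2920 of the 4013 transcripts still passed, and without replicate 3, 2979. Lists passing numbered 9 lower and 5 higher. With an estimated correlation camera passed 0 lower and 0 higher, a setting whose few residual degrees of freedom left little power. With only the mutant in Cy3 camera passed 3 higher, the cause of which was not tested. The fat body, lipid synthesis, glycolysis and apoptosis lists, which did not pass, passed with the mutant in Cy5 only, with the looser filter on missing values and by ranks, and detoxification did with the looser filter (adjusted p between 0.0417 and 0.0499); the cause was not tested. The X-linked genes and the genes near the mutated gene kept their direction and did not pass in any alternative run, with adjusted p between 0.220 and 0.588. The count of dye effects ranged from 0 to 344 over the replicates left out. The lowest correlation between pair means, 0.908, was 0.939 over called genes only, a set chosen for its larger ratios.

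Directions turned in lists that did not pass. The respiratory chain test turned downward with the mutant in Cy3 only (median -0.037), by ranks (0.0065) and without replicate 1, where the medians over the replicates left out ran from -0.067 to 0.065. The dMyc network test turned downward with the mutant in Cy5 only (0.033), by ranks (0.077) and without replicate 2 or replicate 3, with medians from 0.047 to 0.11 over the replicates left out. The germline test turned upward with the mutant in Cy3 only (0.15) and without replicate 1 (medians from -0.096 to 0.11 over the replicates left out), and sex determination did so with the mutant in Cy5 only (0.022). The separate features of ND-B14.5A gave -1.09 and 0.13. The causes of these turns were not tested. Single-gene calls lost in an alternative include kni (without replicate 2), hry and msl-3 (without replicate 2 or 3), pim (mutant in Cy5 only) and nrv3 (0.01 with the looser filter). One feature of Gapdh1 stood at 0.24 and did not pass on its own, and piwi and tra2 passed without replicate 1. tra2 also passed with the replicate as a random block, without and with a dye term (limma, adjusted p = 0.0219 and 0.0426). The level of the mutated gene was not run, and signal over background was not used here, so its limits are not assessed.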

Other observations

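The tests on replicate 1 and on the muscle, neuron and glia genes were chosen after the results were seen, as were the groups of chaperone and purine genes; those on neighbouring genes and on sign patterns were planned before. All 6 measured chaperone genes of the mitochondria and endoplasmic reticulum fell (limma), among them Hsc70-5 at -0.74 ± 0.10 (SD, n = 3), Gp93 at -0.74 ± 0.06 and Trap1 at -0.65 ± 0.04, but Cnx99A, at -0.34 ± 0.14, did not pass without replicate 3 (adjusted p = 0.0574).

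Of 7 measured genes of purine synthesis 3 fell and 2 rose (limma). Prat and Prat2 encode the same enzyme of the first step, yet Prat was at -1.08 ± 0.03 and Prat2 at 3.54 ± 0.47, a difference of 4.62 ± 0.49 over 3 replicates. ras, which encodes the enzyme that commits purines to guanine nucleotides, fell to -1.54 ± 0.13 and CG11089 to -1.21 ± 0.35, while Paics rose to 0.41 ± 0.19.

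Changed genes lay next to each other more often than a random order gives. Of 5295 named genes ordered along the chromosome arms, 655 were lower by at least 1.5-fold and formed 102 neighbouring pairs, against 66 to 97 in the middle 95% of 10000 random allotments (permutation p = 0.0053). The 375 higher genes formed 47 pairs, against 17 to 36 (permutation p = 0.0001, the smallest these permutations can give). A run of 6 lower genes on arm 3R held the lipase family genes CG6296, CG6295, CG17191, CG6283, CG6277 and CG6271, and other runs held the lysozyme genes LysX, LysE and LysS and the tetraspanin genes Tsp42Eg, Tsp42Eh and Tsp42Ei. Chance order is argued against by these counts; cross-hybridisation between similar neighbours and shared regulation were not tested and stay open.

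The DNA replication and cell cycle list had a median of 0.01 in replicate 1 and -0.43 over the means of the others, although single genes such as CycD (-0.52) and Mcm3 (-0.40) were low in replicate 1 too. An equal weakening of all ratios in replicate 1 is argued against as the whole cause, since it would need a slope of replicate 1 on the others of at most 0.5, and over all 6504 transcripts the slope was 0.86 (bootstrap interval 0.85 to 0.87). A weakening of part of the genes stays open: the proteasome list had a median of -0.20 in replicate 1 and -0.46 in the others and the neuron list 0.12 and 0.36, while muscle had 0.55 and 0.47, RNA polymerases I and III -1.43 and -1.29, and the respiratory chain 0.17 and -0.067. Noise of single arrays may contribute. The deviations of the dye-swapped arrays of replicate 1, each taken from a different replicate, correlated at 0.51 across the 23 genes. The interval, 0.14 to 0.77, reaches below the bound of 0.3. A correlation across genes also takes no account of a shift shared by the whole list. It therefore cannot decide whether array noise moved the list median. A difference in the stage of the collected larvae was not tested and stays open.

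Muscle, neuron and glia genes had a joint median of 0.38 (bootstrap interval 0.29 to 0.52). Genes in none of the lists had a median of 0.015, but they are 89% of the named genes on centred arrays, so a value near 0 is built in and cannot exclude centring. A smaller share of fat body RNA alone would raise the genes of all other tissues alike. The digestive enzyme genes of the gut had a median of -0.53 (bootstrap interval -0.79 to -0.27), so it does not account for those genes. Their decrease was known before the test was chosen and may arise within the gut, so it cannot decide why the muscle, neuron and glia genes rose. The medians of the muscle, neuron, glia, hemocyte and tracheal lists spread no more than random allotments of their genes (permutation p = 0.799). This neither argues against a smaller fat body share nor shows that the lists rose alike. A smaller share of fat body RNA or of several tissues, centring, a difference in stage between mutant and control larvae and a change within these tissues stay open.

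The 3 pair means allow 4 sign patterns, too few for a share under 0.05. The observed pattern, 1 of the 4, gave 4013 called transcripts and the highest of the others gave 0 by limma, with at most 15 at an unadjusted p under 0.05.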
